A study of Rattus norvegicus with 115 samples.

How the data were processed

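Gene expression was measured on 115 one-colour Agilent rat arrays, each hybridised with RNA from primary hepatocytes of 1 of 5 female Sprague-Dawley rats (named 277, 293, 302, 361 and 363). The cultures of each rat had been exposed for one day to DMSO vehicle or to 1 of 11 doses of PeCDF or of TCDF, a pentachlorinated and a tetrachlorinated dibenzofuran that act on the aryl hydrocarbon receptor (AHR). This makes 23 groups of up to 5 rats. The group at 0.001 nM TCDF holds 4 rats. Rat 302 has a pair of arrays at 30 nM TCDF, which were averaged, so that 114 units entered the fits. Their scanner files each matched the table column of the other, and the average is the same either way.

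Values came from the series table, which holds log2 values that the authors computed from the processed spot signal and centred on the median of each array. This was read from the files: the largest absolute array median was 0.0011, and for the 85 arrays whose scanner file matched their own column, the column differed from the log2 of the scanner signal by a constant within an SD of 0.09. This could not be read for the 28 samples without a scanner file, which include the vehicle. The scanner files hold signal intensity per spot, which per the file headers was background-subtracted and spatially detrended within the array by Agilent Feature Extraction 9.5.3.1, with spots placed on genome build rn4. There were 87 such files. The 5 vehicle samples and 23 treated samples had none in hand, so the table was the source for all main values. The vehicle arrays are tied by their labels to a companion experiment with TCDD, and their slides and scan dates are unknown. Batch and group can therefore not be told apart for comparisons with the vehicle, and the mean of the 2 lowest doses of the same compound served as a second reference.

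Each array carries 45018 spots, of which 43379 are not controls. Spots of 1 probe were averaged to 41012 probes. Between 49.9% and 82.2% of spots were well above background on the scanner files (median 61.0%), the median raw signal was 323 to 428 units and the median local background 249 to 321 units. Saturated spots numbered 0 to 58 per array, and 0.157% to 1.78% of spots were non-uniform or population outliers. The number of arrays limits the precision. Gene names were updated with the reference table in hand (assembly GRCr8, used for names only and for no position): 10835 probes were matched by accession, 1082 by gene identifier, 5196 by symbol and 3478 by a former symbol, and the name in the files was kept for the other 20421. A symbol resulted for 20690 probes.

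Control spots were left out. A probe was tested if it was well above background on at least 25% of the scanner files, which left 26568 probes, and the probe with the highest mean stood for its gene. This gave 22546 genes and unnamed transcripts, called genes here, of which 11691 have a symbol. The others were counted and not named, since they carry only a transcript or probe identifier.

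All groups were fitted together with limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with the rat as a replicate block and empirical Bayes moderation with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Comparisons were each dose against the vehicle, the linear trend in log10 dose over the 11 doses of a compound without the vehicle, the mean difference of PeCDF minus TCDF over the 9 doses given of both, each of those doses alone, and the difference of the trends over them. The p-values rest on the cultures of 5 rats. Both comparisons at 100 nM share the vehicle arrays, so their results are not independent of each other. Pairing was checked on the deviations of the arrays from their group means: all 114 arrays were closest to an array of the same rat, with a mean correlation across genes of 0.543 within and -0.135 between rats. Genes are not independent replicates in any correlation across genes.

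For potency, Hill curves in log10 dose with an intercept per rat were fitted to the log2 values on a grid of 0.05 log10 units and 6 slopes from 0.5 to 3, with 95% profile intervals, in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). A gene entered if both dose trends were called, both spans were at least 1 log2 unit in the same direction, and both intervals of the half-maximal dose lay inside the dose range. The relative potency is the log10 ratio of the half-maximal doses, TCDF over PeCDF, so that a value above 0 means that less PeCDF was needed. It was also fitted per rat and tested with an exact two-sided sign-flip permutation test, whose smallest p with 5 rats is 0.0625.

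Lists of genes (22, among them markers of 4 other cell types of the liver) were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The comparisons, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, per compound, the 10 largest rises and 8 largest falls at 100 nM among called genes that moved the same way in all 5 rats, every measured member of the list of known AHR-induced genes (the AHR battery), up to 4 members of each other list with the smallest p, the 5 largest called differences each way between the compounds, and for potency the AHR battery, the 10 genes of largest span and the 3 highest and 3 lowest ratios. It gave 118 genes. Genes named outside it are marked in the text as named after their values were seen.

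The alternatives were a fold of at least 2, no replicate block, each rat left out in turn, no probe filter or one at 75% of arrays, quantile normalisation, centring on the 75th percentile, array weights, all probes, the 2 lowest doses as the reference, a fit of only the 2 groups compared, only arrays with a scanner file, slide or scan date as a block, and the scanner files rescaled on their 75th percentile or by normexp (offset 50) and quantile normalisation. For potency they were the vehicle as a dose of 0, the 9 matched doses, a slope of 1, and a common maximum and slope. Without the 5 arrays of lowest weight, slopes from 0.25 and half-maximal doses on the linear scale were chosen after seeing the data. Scanner-based alternatives cannot be run against the vehicle.

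The fits were tested on simulated data, in which 200 genes followed a dose curve with a half-maximal dose of 0.1 nM for PeCDF and 1 nM for TCDF. At 100 nM PeCDF the fit recovered 26.9% of curves with a maximum of 0.5 log2 units, 70.1% of those of 1 and 95.5% of those of 2, and at 100 nM TCDF 35.8%, 73.1% and 93.9%. The mean difference between the compounds found 0%, 25.4% and 72.7% of the same curves, and the difference of trends 0%, 0% and 6.06%, so a shift of this size in potency is rarely found by the latter. False calls numbered at most 10 in each. Simulated potency ratios of 0, 0.5 and 1 gave medians of 0.05, 0.5 and 1. In these simulations the noise was drawn independently for each gene and array. Noise that the genes of an array share was left out, although real arrays of the same slide correlated with 0.334 after fitting. False calls in the real data may therefore be more numerous.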

Results

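Whole-transcript expression was measured in primary hepatocytes of 5 rats after one day with PeCDF or TCDF, dibenzofurans with 5 and 4 chlorines. The series title names the relative potency of dioxin-like compounds as its subject, and both act through AHR, the receptor that also binds dioxin. Each compound was given at 11 doses from 0.00001 to 100 nM, 9 of them the same for both. PeCDF was also given at 0.003 and 0.03 nM, and TCDF at 3 and 30 nM. The vehicle and every dose had 1 array from each of 5 rats, except 0.001 nM TCDF with 4 rats and 30 nM TCDF, where rat 302 had a pair of arrays that were averaged. On the 87 arrays with a scanner file, a median of 61.0% of spots was well above background (49.9% to 82.2%). Values are log2 changes ± SE of the limma fit (n = 5 rats per group) unless said otherwise. The SE and the p-values rest on 1 spread per gene pooled over all 23 groups, not on the spread of the 5 rats at that dose.

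The first question was which genes the highest dose of PeCDF changed against the vehicle. Genes of the AHR battery, the enzymes and regulators long known to be switched on by this receptor, were mostly higher. Aldh3a1, an aldehyde dehydrogenase, rose by 7.65 ± 0.418 (201-fold, adjusted p = 3.12e-28). Nqo1, a quinone reductase, rose 13.4-fold (3.75 ± 0.26), Cyp1a2, a P450 of drug metabolism, 9.44-fold (3.24 ± 0.445; 4.88 on its other probe), and Tiparp, which represses the receptor, 8.24-fold (3.04 ± 0.23). Cyp1a1, the P450 most often used to read AHR activity, rose 5.96-fold (2.58 ± 0.591) from a vehicle level that was already high (9.58 in log2 above the array median), and all of these were higher in 5 of 5 rats. Without rat 277 the change of Cyp1a1 was 1.72. Of 9 measured members 8 rose and 0 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 7.96e-23; adjusted p = 8.95e-06 with an estimated correlation). The exception was the glutathione transferase Gsta3, at 0.46 ± 0.222 (adjusted p = 0.119).

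Among genes outside the battery, Ereg and Areg, both ligands of the epidermal growth factor receptor, rose by 7.46 ± 0.534 and 4.81 ± 0.429 at 100 nM PeCDF. The sodium channel subunit Scn4b rose by 7.68 ± 0.578, the transcription factor Pou3f1 by 6.09 ± 0.364, Ceacam4 by 4.98 ± 0.305 (7.78 on its other probe), the chemokine receptor Ackr3 by 4.26 ± 0.48 and the interleukin receptor subunit Il18rap by 4.13 ± 0.417. Il2rg, the common subunit of several interleukin receptors, stood 6.02 ± 1.92 above the vehicle (adjusted p = 0.0151), but it had no dose trend without the vehicle arrays (0.16 ± 0.205, adjusted p = 0.581) and its level was 7.21 at 0.00001 nM PeCDF against 0.65 with the vehicle. Cyp1b1, a P450 that acts on steroids and carcinogens, had the largest change, 12.76 ± 0.747 on its brightest probe and 8.69 on its other one. At 0.00001 nM PeCDF, Cyp1b1 was well above background on 2 of 4 arrays with a scanner file and Ereg and Scn4b on 0 of 4, so the size of these changes is uncertain. From that dose to 100 nM, Ereg was at least 119-fold higher and Scn4b at least 92.9-fold higher.

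Among the genes with large falls, the fructose transporter Slc2a5 and the glycosyltransferase Galnt18 both fell by 3.51 (11.4-fold, SE 0.339 and 0.575). Ccn2, a secreted matrix protein, fell by 3.18 ± 0.329, and lower as well were the steroid-forming P450 Cyp17a1 (-2.77 ± 0.327) and the glucose transporter Slc2a4 (-2.60 ± 0.362), whose other probe stood at -0.83 and was not called. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 2.46 ± 0.252. The complement receptor C3ar1 (-2.56 ± 0.634, adjusted p = 0.00143) and the transcription factor Hes5 (-2.55 ± 0.831, adjusted p = 0.0175) were below the vehicle but had no trend over the PeCDF doses (-0.09, adjusted p = 0.304, and 0.04, adjusted p = 0.774). All of these were lower than the vehicle in 5 of 5 rats. The lowest value of an array was on average higher with the vehicle (-2.66) than on treated arrays (-3.62), so falls of dim genes are uncertain.

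Genes of bile acid synthesis and transport fell together at 100 nM PeCDF: 12 of 19 measured members fell and 0 rose, both over all genes and adjusted over the list alone (camera adjusted p = 1.85e-09; adjusted p = 0.0821 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, named after its value was seen, fell by 2.36 ± 0.418. The organic anion carriers Slco1a4 (-2.28 ± 0.301) and Slco1a1 (-1.74 ± 0.22) and the bile acid receptor Nr1h4 (-1.10 ± 0.14) were lower too. In glucose metabolism 10 of 16 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 2.46e-06; adjusted p = 0.293 with an estimated correlation). G6pc1, which releases glucose from the liver, fell by 2.25 ± 0.348, and the glycolytic enzyme Pklr (-1.94 ± 0.286) and the regulatory enzyme Pfkfb1 (-1.81 ± 0.257) were lower. Fatty acid oxidation and targets of the lipid sensor PPARA had 11 of 28 lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 2.64e-07; adjusted p = 0.461 with an estimated correlation), among them Cyp4a8 (-1.30 ± 0.206) and Cyp4a2 (-1.15 ± 0.206). In fatty acid and triglyceride synthesis 7 of 20 fell and 2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.729 with an estimated correlation), with Fasn (-1.68 ± 0.277) and Acly (-1.33 ± 0.156) among those lower.

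Of 15 targets of the oxidative stress regulator NRF2, 7 rose and 0 fell, and 9 rose adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.561 with an estimated correlation). Gstp1 rose by 1.53 ± 0.26 and the cystine carrier Slc7a11 by 1.13 ± 0.179. Targets of the drug receptors CAR and PXR split, with 4 of 14 lower, all P450s (Cyp2b21 -1.71 ± 0.18, Cyp2b12 -1.53 ± 0.242, Cyp3a18 -1.35 ± 0.177 and Cyp2b3 -1.26 ± 0.259), and 3 higher, all transporters and named after their values were seen (Abcb1b 0.66, Abcc2 0.56 and Abcc3 0.50). The list as a whole was lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.627 with an estimated correlation).

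The other 15 lists were not called at 100 nM PeCDF by camera. Constitutive P450s had 2 of 18 members higher and 5 lower, although Cyp2a1, a testosterone hydroxylase, rose 12.6-fold (3.66 ± 0.25). Inflammation genes had 6 of 23 higher and 2 lower, with the chemokines Cxcl2 and Cxcl1 up by 2.32 ± 0.31 and 2.31 ± 0.328. The cell cycle list had 7 of 20 higher and 1 lower, the cyclin Ccnd1 (-1.24 ± 0.343; -2.54 on its other probe). Counts of higher and lower were 3 and 2 of 25 for cholesterol synthesis, 2 and 3 of 21 for amino acid and urea metabolism, 2 and 2 of 15 for retinoid metabolism, 4 and 2 of 14 for ER stress, 4 and 3 of 14 for the circadian clock, 0 and 0 of 8 for heme synthesis, 0 and 1 of 7 for the AHR machinery and 0 and 4 of 21 for hepatocyte identity, of which Cebpa was lowest (-0.94 ± 0.134). Adjusted over the list alone, these 11 lists gave 2 and 5, 6 and 2, 7 and 2, 3 and 1, 2 and 3, 2 and 2, 6 and 4, 4 and 3, 0 and 0, 1 and 1, and 0 and 4 in the order named. Markers of other cell types also moved in part: stellate cell and fibroblast markers had 0 of 13 higher and 3 lower (Tagln -1.38 ± 0.187, Sparc -0.65 ± 0.179 and Pdgfrb -0.49 ± 0.147), Kupffer cell and leukocyte markers had 1 of 14 higher (Cd14 0.59 ± 0.135) and 1 lower (Lyz2 -0.96 ± 0.183), endothelial markers had 2 and 2 of 9, and cholangiocyte markers 1 and 1 of 5. Adjusted over the list alone, only the stellate list differed, with 4 lower. The lower cholangiocyte marker was Krt19 (-2.03 ± 0.511). With a scanner file, it was well above background on 2 of 4 arrays at 0.00001 nM PeCDF and not on any of 4 at 100 nM. The size of its fall is therefore uncertain.

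**Figure D1:**
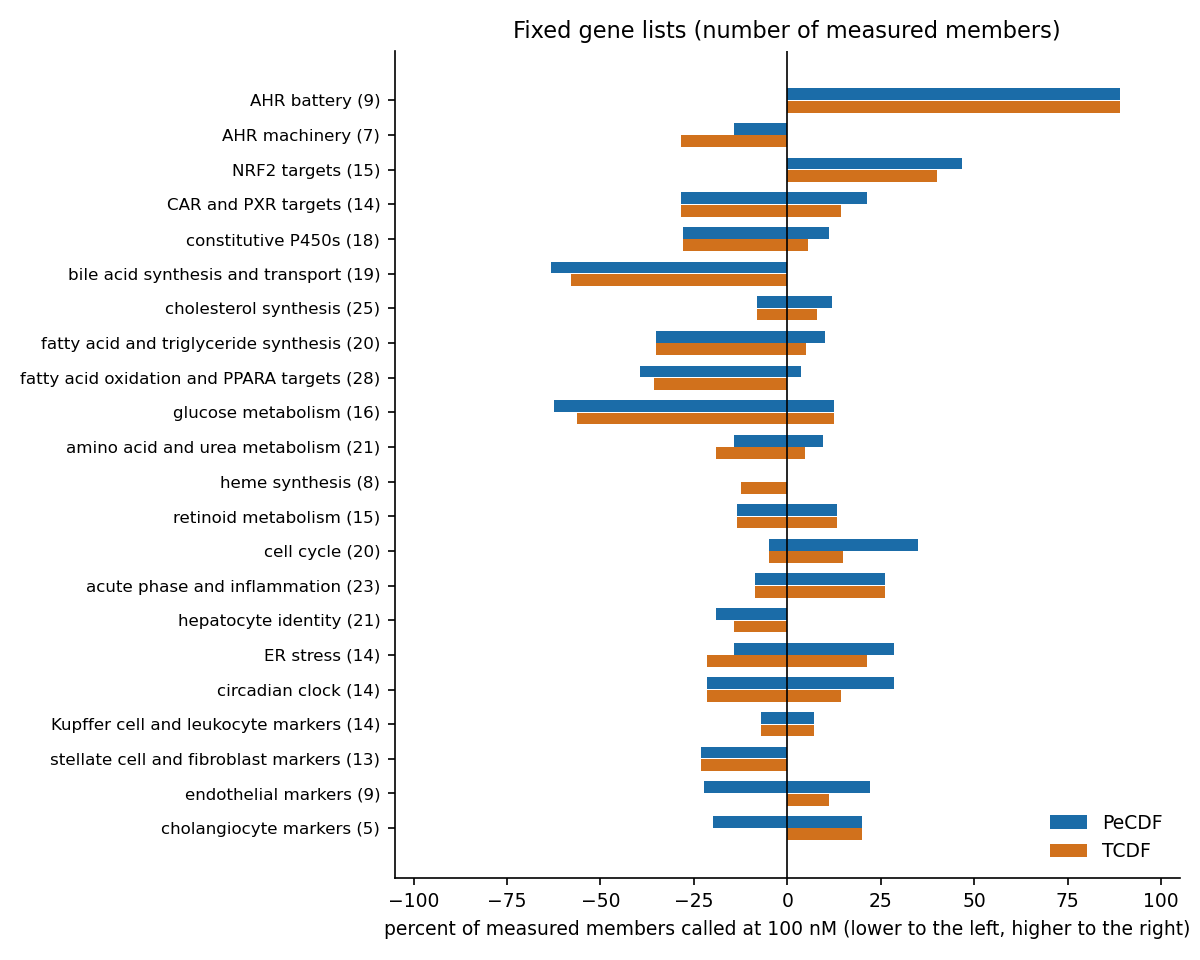
Percentage of the measured members of each of the 22 gene lists that were called lower (left) or higher (right) at 100 nM against the vehicle, for PeCDF and TCDF. The AHR battery has 8 of 9 members higher with both compounds, and bile acid synthesis and transport has 12 and 11 of 19 lower.

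In all, 5293 of 22546 genes were called at 100 nM PeCDF, 3305 higher and 1988 lower, and 1203 of them changed at least 2-fold (514 higher, 689 lower). The median of all genes stood at 0.105, so small rises are best read against it. Without the rat as a replicate block 558 genes were called, without rat 277 3374, without rat 361 3427, and with a fit of only these 2 groups 2416. With the 2 lowest PeCDF doses in place of the vehicle 7206 genes were called (5544 higher, 1662 lower), and there Hes5 was no longer lower (0.029). Leaving out 1 rat ended the calls of Sparc (-0.35 without rat 277), Ccnd1 (-0.99 without 277, -1.01 without 363), Pdgfrb (-0.44 without 302, -0.41 without 361), Hes5 (-2.25 without 302, -2.23 without 361, -2.36 without 363) and Il2rg (5.12 without 361).

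The same question was asked of 100 nM TCDF, against the same vehicle arrays, so likeness to the changes with PeCDF is in part built in. Aldh3a1 rose by 7.14 ± 0.418 (142-fold, adjusted p = 4.34e-26), Nqo1 by 3.46 ± 0.26 (11.0-fold), Cyp1a2 by 3.14 ± 0.445 (8.79-fold; 4.63 on its other probe), Tiparp by 2.59 ± 0.23 (6.00-fold) and Cyp1a1 by 2.35 ± 0.591 (5.10-fold), each in 5 of 5 rats. Without rat 277 the change of Cyp1a1 was 1.505. Scn4b rose by 7.32 ± 0.578, Ereg by 6.32 ± 0.534, Pou3f1 by 5.59 ± 0.364 and Areg by 4.08 ± 0.429. Cyp1b1 rose by 12.18 ± 0.747 on its brightest probe. At 0.00001 nM TCDF, Scn4b, Ereg and Cyp1b1 were each well above background on 1 of 4 arrays, so the size of these 3 changes is uncertain. Lower were Slc2a5 (-3.23 ± 0.339), Galnt18 (-2.98 ± 0.575), Ccn2 (-2.96 ± 0.329), Cyp17a1 (-2.77 ± 0.327), the secreted morphogen Ihh (-2.44 ± 0.346, with 2 of 3 probes called and the smallest change -0.45) and the alcohol dehydrogenase Adh6a (-2.45 ± 0.569), each in 5 of 5 rats. With PeCDF, Adh6a changed sign when the 2 lowest doses replaced the vehicle. With TCDF it did not, but the vehicle arrays are the same, so the size of its fall is uncertain. Il2rg (4.55 ± 1.92, adjusted p = 0.0893), C3ar1 (-1.15 ± 0.634, adjusted p = 0.21) and Hes5 (-1.84 ± 0.831, adjusted p = 0.116) were among the genes called with PeCDF that missed the threshold with TCDF, and none of them was called as different between the compounds at this dose.

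Among the lists, 9 were called at 100 nM TCDF. The AHR battery had 8 of 9 members higher, also when adjusted over the list alone (camera adjusted p = 6.99e-25; adjusted p = 3.17e-06 with an estimated correlation). Bile acid synthesis and transport had 11 of 19 lower, also adjusted over the list alone (camera adjusted p = 6.22e-09; adjusted p = 0.103 with an estimated correlation), with Slco1a4 at -2.07 ± 0.301 and Slco1b2, another hepatic anion carrier, at -1.58 ± 0.242. Glucose metabolism had 9 of 16 lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p = 2.46e-06; adjusted p = 0.293 with an estimated correlation), fatty acid oxidation 10 of 28 lower, the same adjusted over the list alone (camera adjusted p = 2.93e-07; adjusted p = 0.47 with an estimated correlation), and fatty acid synthesis 7 of 20 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.00428; adjusted p = 0.66 with an estimated correlation). NRF2 targets had 6 of 15 higher, also adjusted over the list alone (camera adjusted p = 0.00469; adjusted p = 0.645 with an estimated correlation), and CAR and PXR targets 4 of 14 lower and 2 higher (5 and 2 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.66 with an estimated correlation). Amino acid and urea metabolism had 4 of 21 lower, among them the urea cycle enzyme Otc (-1.20 ± 0.189), and 1 higher, Gnmt (0.76 ± 0.268), and 5 and 2 adjusted over the list alone (camera adjusted p = 0.0316; adjusted p = 0.688 with an estimated correlation). Hepatocyte identity had 3 of 21 lower, also adjusted over the list alone: Cebpa (-0.87 ± 0.134), Nr1i2 (-0.80 ± 0.24) and Foxa3 (-0.56 ± 0.16), all transcription factors of the liver (camera adjusted p = 0.0177; adjusted p = 0.688 with an estimated correlation). Of the stellate cell and fibroblast markers 3 of 13 were lower (Tagln -1.27 ± 0.187, Sparc -0.71 ± 0.179 and Col5a2 -0.37 ± 0.123), but that list and the other 12 were not called, with camera adjusted p from 0.0654 up. Leaving out 1 rat ended the calls of Adh6a (-1.71 without rat 361), Nr1i2 (-0.71 without 277, -0.51 without 361), Foxa3 (-0.53 without 302), Sparc (-0.49 without 277, -0.57 without 361), and of Gnmt and Col5a2 without rat 277, 302, 361 or 363.

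With 100 nM TCDF 3903 genes were called, 2003 higher and 1900 lower, 891 of them by at least 2-fold (309 higher, 582 lower). Centred on the 75th percentile, where the median of all genes stood at 0.116, 5938 were called (3861 higher, 2077 lower), after quantile normalisation 6881 (4379 higher, 2502 lower), and against the 2 lowest TCDF doses 5898 (3926 higher, 1972 lower). Without the rat as a replicate block 269 were called, without rat 302 2156, without rat 361 2255, and with a fit of only these 2 groups 1667.

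Lower doses were compared with the vehicle to find the lowest dose at which a gene was called. A call depends on the SE and on the adjustment within each dose, so this need not be where the response began. For Cyp1a1, Cyp1a2 and Ugt1a6 the fitted half-maximal dose (0.00224, 0.0251 and 0.0282 nM of either compound) lay below the lowest dose called. For Nqo1, Cyp1b1, Aldh3a1 and Tiparp it lay above. The lowest dose at which a gene was called, there and at every higher dose, was 0.03 nM PeCDF and 0.1 nM TCDF for Cyp1a1 (2.41 ± 0.591 and 2.48 ± 0.591), Nqo1 (1.41 ± 0.26 and 1.24 ± 0.26) and the glucuronosyltransferase Ugt1a6 (1.45 ± 0.256 and 1.67 ± 0.256). TCDF was not given at 0.03 nM, so for these genes the step from 0.03 to 0.1 nM shows no difference between the compounds. Cyp1a2, Cyp1b1 and Aldh3a1 were called from 0.1 nM of both compounds, and Gsta2 from 0.3 nM of both. Tiparp and Areg were called from 0.1 nM PeCDF and 1 nM TCDF, Pou3f1 and Scn4b from 0.1 and 0.3 nM, Ereg from 0.3 and 1 nM and Ackr3 from 10 and 30 nM. Among genes that fell, Slc2a5 was called from 0.3 nM of both and Ccn2 and Slc2a4 from 1 nM of both. G6pc1 was called from 0.3 nM PeCDF and 1 nM TCDF, and Slco1a4 and Cyp17a1 from 1 nM PeCDF and 0.3 nM TCDF.

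**Figure D2:**
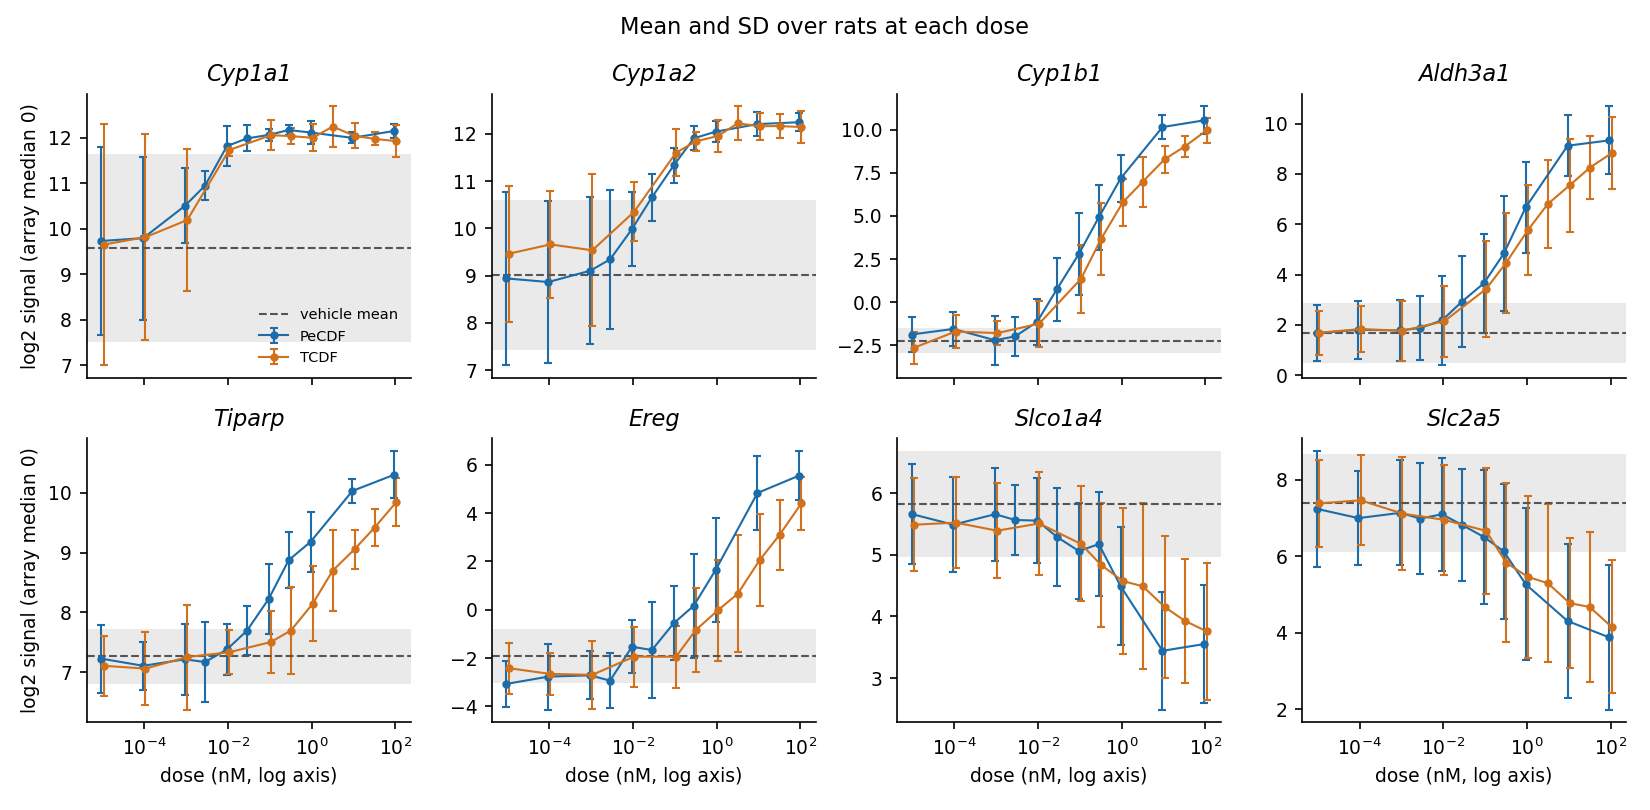
Log2 level of 8 named genes against the dose of PeCDF and TCDF on a log axis, as the mean over rats with the SD, with the vehicle mean as a dashed line and its SD as a grey band. Tiparp and Ereg rise at lower doses of PeCDF than of TCDF, while the curves of Cyp1a1 and Cyp1a2 lie close together.

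The number of called genes was 158 at 0.1 nM PeCDF, 334 at 0.3, 1938 at 1 and 3497 at 10 nM. It was 237 at 0.1 nM TCDF, 640 at 0.3, 1076 at 1, 1761 at 3, 2103 at 10 and 2905 at 30 nM. At 0.001 and 0.003 nM PeCDF limma called 0 genes, with 1660 and 1997 at an unadjusted p under 0.05. The lowest doses were not free of calls, with 25 and 81 genes at 0.00001 and 0.0001 nM PeCDF and 3 and 163 at the same doses of TCDF, 149 of the latter lower; the median of all genes was -0.118 at 0.0001 nM PeCDF. The 3 genes at 0.00001 nM TCDF include the sterol-binding Osbpl10 (-2.27 ± 0.47), named after its value was seen, and 2 without a symbol. In all, 11 of 20 lower doses had 100 or more calls, 7 without rat 361, and 2 without the replicate block.

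**Figure D3:**
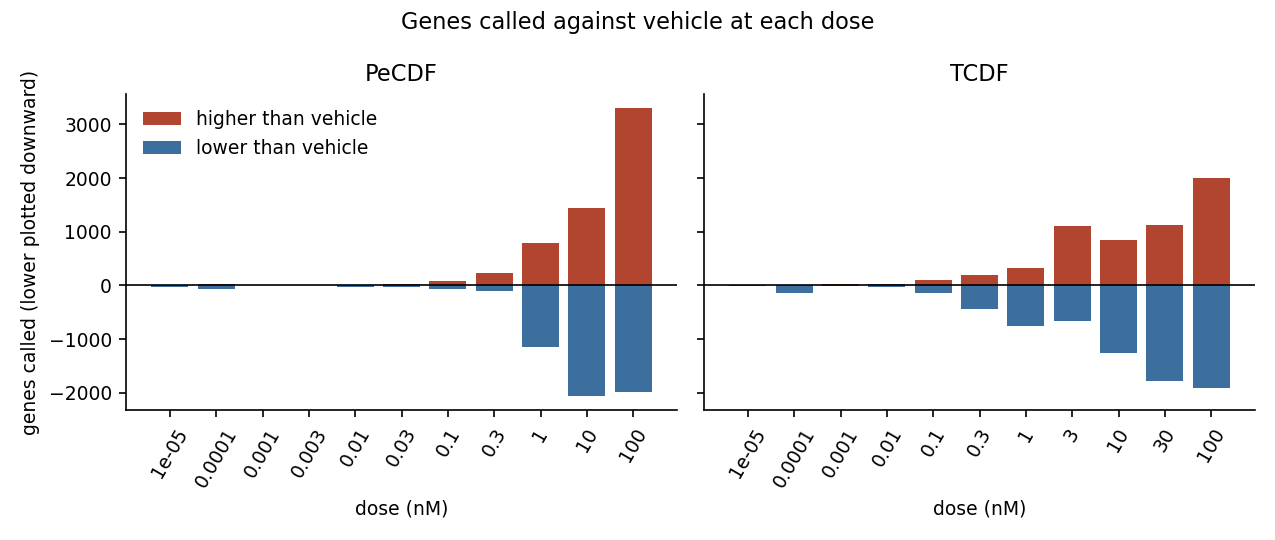
Number of genes called higher and lower against the vehicle at each dose of PeCDF and TCDF, in nM. Calls stay at 163 or fewer up to 0.01 nM and reach 5293 for PeCDF and 3903 for TCDF at 100 nM.

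Dose trends over the 11 doses of a compound do not use the vehicle arrays. Cyp1b1 rose by 2.17 log2 units per 10-fold dose of PeCDF and 2.01 of TCDF, Pou3f1 by 0.96 and 0.81, Ereg by 1.35 and 0.97 and Aldh3a1 by 1.28 and 1.15. Ccn2 fell by 0.53 and 0.46, Slc2a5 by 0.51 and 0.50, and Cyp17a1 by 0.45 and 0.46. All 9 members of the AHR battery rose with both compounds (camera adjusted p = 3.51e-21 and 5.14e-22; adjusted p = 2.1e-05 and 1.36e-05 with an estimated correlation). Of 19 bile acid genes 14 fell with each, also when adjusted over the list alone (camera adjusted p = 2.52e-11 and 9.06e-11; adjusted p = 0.0377 and 0.0474 with an estimated correlation).

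PeCDF gave 9190 genes with a trend (6561 rising, 2629 falling) and TCDF 8403 (5484 rising, 2919 falling). Centred on the 75th percentile the split was 4367 rising and 4422 falling for PeCDF and 4283 and 4329 for TCDF, and after quantile normalisation 5093 and 4085, and 4995 and 4175, so the surplus of rising genes rests on the scaling. Genes rising with both compounds numbered 4915 (1596 expected if the calls were independent) and genes falling with both 2163 (340 expected), while 0 genes went in opposite directions and 2112 and 1325 were called for PeCDF or TCDF alone. The slopes of the compounds correlated across genes with r = 0.902, against at most 0.484 in 99 shuffles of the doses within rats, although genes are not independent replicates. Within the 5 combinations of scan date and compound with enough arrays, 67.2% to 96.2% of the called genes had the same sign, the median slope of the AHR battery was 0.324 to 1.15 and that of the bile acid genes -0.295 to -0.121. These arrays were also part of the fit that called the genes, so some of the likeness in sign is built in. Without the replicate block, 3347 and 2187 genes had a trend.

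The next question was whether the compounds differed at the 9 matched doses. The differences that passed the test were small, and the largest had PeCDF higher in 5 of 5 rats. Ereg was higher by 0.86 log2 units on average (95% interval 0.50 to 1.21, adjusted p = 0.0337), a mean that includes low doses at which its signal was near background, Areg by 0.63 (0.34 to 0.92, adjusted p = 0.0493), Pou3f1 by 0.55 (0.30 to 0.79, adjusted p = 0.0493) and Tiparp by 0.51 (0.36 to 0.67, adjusted p = 4.08e-05). The stress-response gene Ier3 was higher by 0.25 (0.14 to 0.36) and the transcription factor Zhx3 lower by 0.19 (-0.28 to -0.10), both with an adjusted p = 0.0493. The remaining called genes with a symbol, named after their values were seen, were Mis12 (0.24), Arhgef7 (0.22) and Dhx33 (0.22).

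For other genes of the AHR battery the interval of the difference included 0 or the adjusted p missed the threshold. Adjusted over the list alone, a comparison made after results were seen, 4 of 9 members were higher with PeCDF, Tiparp included, and 0 lower. The difference was 0.09 for Cyp1a1 (-0.31 to 0.48), -0.23 for Cyp1a2 (-0.52 to 0.07), 0.09 for Gsta2 (-0.06 to 0.25), 0.11 for Ugt1a6 (-0.06 to 0.28), 0.26 for Nqo1 (0.09 to 0.44, adjusted p = 0.146), 0.42 for Aldh3a1 (0.15 to 0.70, adjusted p = 0.146) and 0.80 for Cyp1b1 (0.30 to 1.29, adjusted p = 0.131). Among genes that fell, it was -0.06 for Slco1a4 (-0.26 to 0.14), -0.15 for Slc2a5 (-0.38 to 0.07), -0.07 for Ccn2 (-0.29 to 0.15) and -0.00 for Fasn (-0.19 to 0.18). For 22516 of 22546 genes the interval lay within 1 log2 unit of 0, and the median interval reached 0.115 to either side. At 100 nM alone this held for 19539 genes, and the median interval reached 0.341. The mean runs over all matched doses, and the interval of Tiparp also lay within this bound. The bound therefore does not exclude a difference in potency.

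In all 15 genes were called on the mean difference, 11 higher with PeCDF and 4 lower, 6 of them without a symbol, and 3344 had an unadjusted p under 0.05. Centred on the 75th percentile the split was 3 higher and 15 lower, and after quantile normalisation 6 higher and 10 lower. Areg, Pou3f1 and Ier3 missed the threshold with the former (0.58, 0.50 and 0.20, each with an adjusted p = 0.0595), and so did Areg (adjusted p = 0.0683) and Ier3 with the latter, while Tiparp and Ereg passed with both. Without rat 361, Ereg (0.78, adjusted p = 0.127), Areg (0.41, adjusted p = 0.436) and Pou3f1 (0.52, adjusted p = 0.194) missed the threshold. So did Ereg and Areg without rat 363 (adjusted p = 0.0562 and 0.0669), and Pou3f1 without rat 277 or 302 (adjusted p = 0.0616 and 0.0673). Ier3 and Zhx3 missed it without rat 293, 361 or 363. The count was 278 without rat 277, 192 without rat 302, 33 without rat 293, 8 without rat 363 and 5 without rat 361, and 1 with the scan date as a block. It was 2370 with array weights and 1137 without the 5 arrays of lowest weight, the latter chosen after seeing the data, so the number of genes that differ is not settled. Tiparp was called in each of these fits, with differences of 0.46 to 0.62. Without the replicate block 0 genes were called and Tiparp stood at 0.51 (adjusted p = 0.273). At single doses, 1 gene was called at 0.3 nM, Tiparp (1.18, 0.72 to 1.63; median of all genes 0.136), 1 without a symbol at 1 nM, and 5 at 10 nM: Ereg (2.78, 1.72 to 3.84), Ackr3 (2.62, 1.67 to 3.57), 1 without a symbol and, named after their values were seen, Apbb2 (0.66, 0.39 to 0.93) and Celsr3 (-1.5, -2.14 to -0.86). At the other doses limma called 0, with 669 genes at 0.00001 nM, 1000 at 0.0001, 332 at 0.001, 283 at 0.01, 2085 at 0.1 and 589 at 100 nM at an unadjusted p under 0.05. The dose trend differed for 0 genes (696 at an unadjusted p under 0.05), and for 1 gene without rat 277, 293 or 363.

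Relative potency was read from the half-maximal doses, which are the doses at the midpoint of the fitted log2 change. For a rising gene of large span this dose lies below the dose at the midpoint of the signal itself. The doses of genes with unlike spans are therefore not directly comparable. Cyp1a1 needed 0.00224 nM of either compound (95% interval 0.000447 to 0.00631 nM for PeCDF and 0.000141 to 0.0112 nM for TCDF), Cyp1a2 0.0251 nM of either and Ugt1a6 0.0282 nM of either. Nqo1 needed 0.0891 nM PeCDF and 0.178 nM TCDF, Cyp1b1 0.224 and 0.447 nM, and Aldh3a1 0.501 and 0.891 nM. Tiparp needed 0.282 nM PeCDF (0.158 to 0.631) and 4.47 nM TCDF (1.58 to 10), and Ereg 1 nM (0.562 to 1.78) and 7.08 nM (3.16 to 20). The intervals do not overlap for these genes, nor for 1 without a symbol, 3 of 440 in all. At the lowest doses Ereg and Cyp1b1 were near background, so their half-maximal doses rest on a lower level set in part by noise and are uncertain.

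**Figure D4:**
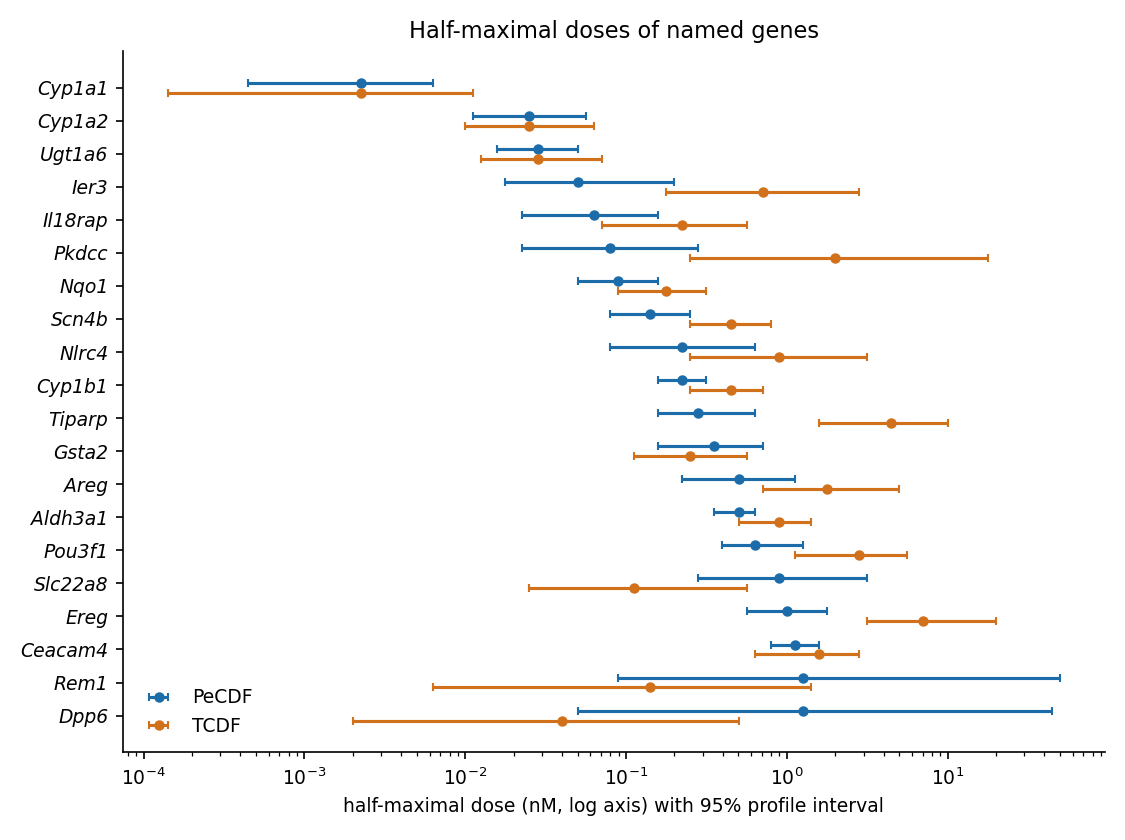
Half-maximal dose of PeCDF and TCDF in nM on a log axis for 20 named genes, fitted to log2 values, with 95% profile intervals. The intervals of Tiparp and Ereg do not overlap, while those of Cyp1a1, Cyp1a2 and Ugt1a6 share the same centre.

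Fitted in each rat, the log10 ratio of TCDF over PeCDF had a mean of 0.19 for Cyp1a1 (SD 0.545, n = 5, above 0 in 3 of 5 rats). That mean for Cyp1a1 was -0.025 without rat 361, 0.0625 without rat 277, 0.312 without rat 293, 0.04 with the vehicle as a dose of 0 and -0.08 with the scanner files on their 75th percentile, so its sign is not settled. For genes called as different between the compounds it was 1.18 for Tiparp (SD 0.767), 1.00 for Ereg (SD 0.605), 0.75 for Pou3f1 (SD 0.461), 0.68 for Areg (SD 0.506) and 1.45 for Ier3 (SD 0.942), each above 0 in 5 of 5 rats. The other genes named for the most extreme ratios had 1.68 for Pkdcc (SD 1.241, above 0 in 4 of 5 rats), -1.17 for Rem1 (SD 0.704, 0 of 5), -0.85 for Dpp6 (SD 1.4, 1 of 5) and -0.25 for Slc22a8 (SD 1.515, 1 of 5). As these genes were picked for their differences or ratios, no p is given for them. Of the 7078 genes with both trends, 440 met the entry rule, 187 rising and 253 falling. Their median log10 ratio was 0.1 (1.26-fold; quartiles -0.15 and 0.35), with 261 genes above 0, 159 below and 20 at 0. The median half-maximal dose was 0.501 nM for both compounds, and simulated genes with a true ratio of 0 gave a median ratio of 0.05. A higher potency of PeCDF over these genes is therefore not shown. The median ratio was 0.25 for genes that rose and 0 for genes that fell.

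The median differed between rats, and it was -0.375 in rat 277, -0.5 in 293, 0.6 in 302, 0.85 in 361 and 0.3 in 363 (mean 0.175, SD 0.594, above 0 in 3 of 5, exact two-sided p = 0.5625). For genes that rose the mean was 0.26 (SD 0.345, exact p = 0.25) and for genes that fell 0.02 (SD 0.934, exact p = 1). Without rat 361 the median over genes was -0.05, without rat 302 0, without rat 277 0.2, and with the scanner files on their 75th percentile -0.25. Slopes sat at the lowest value tried in 177 PeCDF and 332 TCDF fits. Allowing slopes from 0.25 left 193 genes with a median of 0.1, a slope of 1 gave a median of 0 over 426 genes, and half-maximal doses on the linear scale gave 0 over 361.

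**Figure D5:**
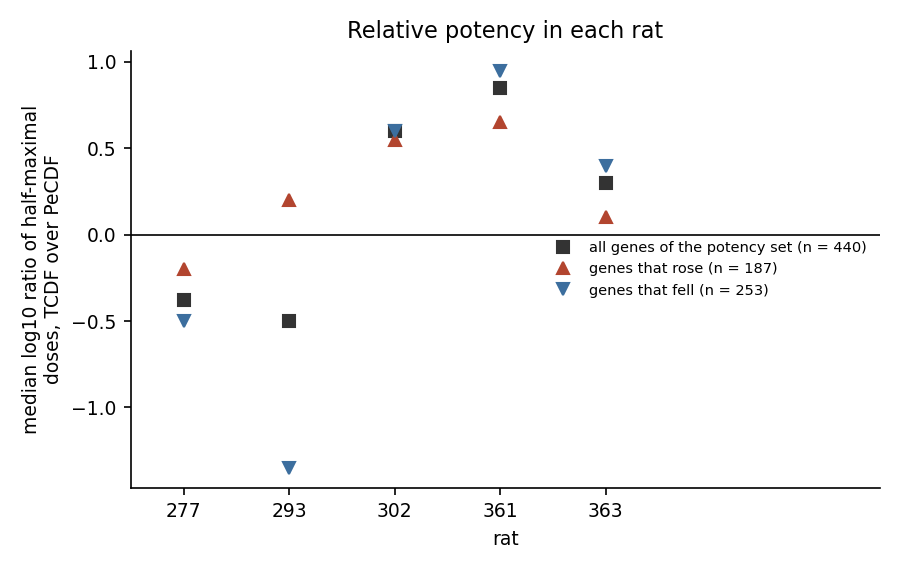
Median log10 ratio of half-maximal doses, TCDF over PeCDF, in each of the 5 rats for all 440 genes, the 187 that rose and the 253 that fell. Values for all genes run from -0.5 in rat 293 to 0.85 in rat 361, on both sides of 0.

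Rats also differed in their level of Cyp1a1 with the vehicle, which was 6.09 in rat 277 and 10.58, 10.50, 11.32 and 9.39 in rats 293, 302, 361 and 363 (SD 2.07). The mean over the 2 lowest doses in rat 277 was likewise low, 6.34 for PeCDF and 5.45 for TCDF. At 100 nM the rats lay close together, at 12.02 to 12.42 with PeCDF (SD 0.156) and 11.42 to 12.38 with TCDF (SD 0.348), so that the rise of Cyp1a1 was largest in rat 277.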

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

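Of the tests in this part, that of the array offsets for potency and that of the centring for rising genes were chosen after their results were seen. Among 256 groups of 5 rats, 7 held a rat far from the other 4, while chance gives about 1 in 20, or 12.8. At 100 nM TCDF, rat 293 changed less than the others in Aldh1a2 (0.07, others 2.35 to 3.16), Cyp3a18 (-0.27, others -1.73 to -1.38) and Gys2 (-0.46, others -1.31 to -1.14), and at 100 nM PeCDF in Pklr (-0.35, others -2.65 to -2.11). Rat 277 rose more in Cyp1a1 with TCDF (5.74, others 0.72 to 2.04). Rat 361 had lower Ncoa2 than with the vehicle under PeCDF (-3.72, others -0.18 to 0.42) and TCDF (-4.04, others -0.5 to 0.77), a pair of values that share the vehicle array of this rat. No explanation of these values was tested.

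The first pattern weighed is a relative potency that differs between rats, from -0.5 in rat 293 to 0.85 in rat 361. Array offsets from the centring would push rising and falling genes to opposite sides of their means over rats. In 4 of 5 rats both deviated to the same side, but rat 293 counts here by a narrow margin. Its median was 0.2 for rising genes (mean 0.26) and -1.35 for falling genes (mean 0.02), so this count does not decide on offsets. Other scalings left an SD of at least 0.557 against 0.594, and with the scan dates subtracted the SD was 0.597 against 0.567. This argues against the scaling and the scan dates as the whole cause of the spread. Subtracting the scan dates did move rat 302 from 0.4 to -0.075, so that 2 of 5 rats stayed above 0, and the place of single rats depends on it. With 1 culture per rat and dose, noise between cultures and a difference between animals stay open, and no biological explanation was tested.

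The second pattern is that more genes rose than fell with dose. It was not confined to dim probes, since among probes well above background on at least 75% of arrays the smaller share of rising genes was 66.5%, against 65.3%. The values had been centred on all probes before this filter. The test therefore cannot tell whether dim probes shifted the centre of the arrays. Centred on the 75th percentile, the larger share was 49.7%, so the median centring of the values may account for the surplus. Which centring is nearer to the true balance stays open, as the arrays hold no outside standard that was used here.

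The third pattern is the higher Tiparp, Ereg, Areg and Pou3f1 with PeCDF at matched doses. The mean difference of these 4 genes was 0.655 with the scan date as a block (0.63 without it on the same arrays) and 0.59 centred on the 75th percentile, against 0.637. This argues against scan dates and array offsets as the whole cause of this mean. Without any one rat it was at least 0.54. The genes were picked for their differences and were higher with PeCDF in 5 of 5 rats, so leaving out 1 rat could hardly remove the mean. That test therefore says little about the cells of one rat. The calls of Ereg, Areg and Pou3f1 did not all hold: on the arrays with a scanner file each missed the threshold without the scan date as a block (0.88, 0.54 and 0.58; adjusted p = 0.115, 0.191 and 0.143) and with it (0.99, 0.53 and 0.62; adjusted p = 0.155, 0.431 and 0.336), and so did each without rat 361, where Areg went from 0.63 to 0.41. A higher potency of PeCDF for these genes may underlie the difference, a hypothesis found and tested on the same data. An error in the nominal doses would shift all genes alike. The log10 ratio was 0 for Cyp1a1, Cyp1a2 and Ugt1a6, -0.15 for Gsta2, 0.25 for Aldh3a1, 0.3 for Nqo1 and Cyp1b1 and 1.2 for Tiparp. These ratios differ, but Tiparp was picked for its difference and the sign for Cyp1a1 is not settled. A dose error had no test of its own and is not excluded.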

How the results depend on the processing

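The alternative without the 5 arrays of lowest weight was chosen after seeing the data. Causes were not tested unless the setting itself shows them, as fewer groups or arrays do. Genes called at 100 nM PeCDF (5293) and TCDF (3903) numbered 1203 and 891 with a fold of at least 2, 558 and 269 with no replicate block, and 2416 and 1667 with only the 2 groups compared. For TCDF they numbered 6881 after quantile normalisation, 5938 centred on the 75th percentile and 5898 with the 2 lowest doses as reference. Without one rat the range was 3374 to 5256 and 2156 to 4154. Trends fell to 3347 and 2187 genes with no replicate block. The mean difference between compounds (15 genes) moved most: 0 with a fold of at least 2 and 0 with no replicate block, 2 with no probe filter and 23 with the filter at 75% of arrays, 2370 with array weights, 1137 without the 5 arrays of lowest weight, 9 with all probes, 2 with only arrays that have a scanner file, 2 with the slide as a random block, 1 with the scan date as a fixed block, 1 with the scanner files on their 75th percentile and 1 with normexp and quantile on them, and 5 to 278 without one rat. The difference of trends (0 genes by limma, 696 at an unadjusted p under 0.05) was 2 with array weights and 0 to 1 without one rat. Lower doses with 100 or more calls (11) numbered 2 with no replicate block, 20 with no probe filter, 17 after quantile normalisation, 6 with only the 2 groups compared, and 7 to 11 without one rat. Gene lists called (7 and 9) numbered 4 and 5 with no replicate block and 1 and 1 by camera with an estimated correlation. With the 2 lowest doses as reference, 3 genes lower at 100 nM PeCDF had the opposite sign: Adh6a (0.117), Hes5 (0.029) and Tie1 (0.08). Of the other values of named genes, 3199 kept their side of the threshold, 381 lost and 40 gained a call. Direction was compared only for values called in the main fit. Dim genes limit the data: as few as 49.9% of spots were well above background on an array, and the vehicle arrays have no scanner file to tell this by. The lowest value of an array averaged -2.66 (SD 0.73) on the vehicle arrays and -3.62 (SD 0.57) on the treated arrays. A dim gene can therefore seem lower than the vehicle at any dose, and such falls are uncertain.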

Other observations

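The splits for the counts at 100 nM, for the trends and for both differences between compounds were chosen after their results were seen. Lists were also compared on the mean difference at matched doses, again after results were seen. Cholesterol synthesis was higher with PeCDF (camera adjusted p = 9.74e-05; adjusted p = 0.531 with an estimated correlation), with 0 members called over all genes and 8 adjusted over the list alone, among them Hsd17b7 (0.16) and, named after their values were seen, Mvd (0.18), Cyp51 (0.18) and Acat2 (0.16). Endothelial markers were lower with PeCDF, with a median of -0.146 (camera adjusted p = 0.000565; adjusted p = 0.0104 with an estimated correlation), and 2 members passed adjusted over the list alone. Stellate cell and fibroblast markers were lower too (camera adjusted p = 9.74e-05; adjusted p = 0.0933 with an estimated correlation). Of the other lists, AHR battery (camera adjusted p = 0.00247; adjusted p = 0.362 with an estimated correlation) and NRF2 targets (0.0219 and 0.631) were higher, and constitutive P450s (0.00178 and 0.513), Kupffer cell markers (0.011 and 0.513) and bile acid genes (0.0219 and 0.631) lower.

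Each count was set against 100 splits of the same arrays, the real one included. At 100 nM PeCDF 1 split, the real one, gave as many as 5293 genes and the highest other gave 2766, and for TCDF 1 split gave as many as 3903 with 2782 as the highest other, a share that excludes chance over all splits drawn. The 5 rats pair the arrays, however, and the 16 splits that part every pair are too few for a share under 0.05; there the real counts stood against a highest other of 2766 and 2193. For trends, 1 split reached 9190 with PeCDF (highest other 5543) and 1 split reached 8403 with TCDF (highest other 0), and for lower doses 1 split reached 11 (highest other 4), which excludes chance in each. For the mean difference 3 splits, the real one included, gave 15 genes or more, the highest other 2163. This share is under 0.05, but another split called far more genes than the real one. Chance is therefore not excluded, and the high count points to a structure of the samples. For the difference of trends the real count is 0, which all 100 splits reach by construction, so this comparison says nothing about chance. The highest other split gave 3344 and points to a structure of the samples. For gene lists, 32 splits reached 7 with PeCDF (highest other 12) and 11 splits reached 9 with TCDF (highest other 11), so chance cannot be excluded for the number of lists called.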
